A study of Amphimedon queenslandica with 144 samples.

How the data were processed

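The measurements were transcript counts from 144 single animals of the demosponge Amphimedon queenslandica, each sequenced as its own library. Swimming larvae made up 117 of the animals and settled post-larvae, which had attached to a surface, made up 27. Per the labels, libraries were made by CEL-Seq2, a method that tags the 3' end of each polyadenylated molecule with an animal barcode and a short random identifier, and then amplifies the RNA linearly. Per the labels' series text, reads were split by barcode and processed with the public CEL-Seq pipeline, and they were assigned to the Aqu2.1 gene models. The aligner, its settings and the genome build are not given in the sources used here. Per the name given to the deposited count table, both lanes were added together and the rows of spike-in RNA and of bacteria were taken out.

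The authors deposited 1 table of whole-number counts with 47411 features in rows and the 144 animals in columns. Aqu2.1 gene models made up 44016 of the features, and 3395 features had identifiers of another form that the labels do not describe. The highest count was exactly 8192, which equals 2 lanes of 4096 possible identifiers of 6 bases, so the counts behave as counts of identifiers with a ceiling. That ceiling was reached by 39 values. A count above 4096 occurred in 4275 values from 183 features, and those features held 22.1% of all counts. Near the ceiling 2 molecules often share an identifier, so that high counts and their fold changes are compressed. No columns were identical.

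Total counts ran from 541737 to 4692279 per animal, with a median of 2011368.5. The number of features with a count ran from 13033 to 21852, with a median of 18768. Libraries had been made in 3 batches labelled T, K and C with 48 animals in each. Mean totals were 2094943 ± 669999 counts (SD, n = 48) in T, 2006630 ± 476977 (SD, n = 48) in K and 1877257 ± 419623 (SD, n = 48) in C. Batch was unevenly spread over the groups. Of the 27 settled animals 25 were in C, whereas 1 of 36 seawater larvae was in C. With 3 counts as the smallest level taken as different from 0, a fold against a group without any count is given as a lower bound from 3 counts over that whole group. Such bounds cover counting error only.

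Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (robust fit) in R 4.3.3. The low-count filter of edgeR, applied by group, kept 14950 features, of which 424 had the other form of identifier, and these held 99.4% of all counts. Library sizes were scaled by the trimmed mean of M-values (factors 0.644 to 1.20). The model held a mean for each of the 17 groups and a term for batch, and all 144 animals entered 1 fit. A gene was called changed when its Benjamini-Hochberg adjusted p was below 0.05 in that comparison. Tests were 2-sided. Comparisons averaged over ages or algae give each group equal weight. Standard errors of log2 fold changes are the fold change divided by the square root of F. CPM values, counts scaled to a common library total, use the scaled library sizes and are not corrected for batch. In simulated counts with the real means and library sizes, 2-fold changes were recovered for 53% of genes in the settled comparison, 62% in the A. fragilissima comparison and 26% in the comparison of ages 10 and 0.5 h. For 4-fold changes the shares were 79%, 95% and 60%. False calls made up 6.38%, 10.3% and 9.47% of the calls in those simulations. All animals were given the same spread per gene there. Settled animals in fact varied more than swimming larvae along the first principal component, described below. The shares for the settled comparison may therefore not hold in the real counts. At a single induction age, simulated with Mesophyllum sp. at 3 h, recovery was 26% and 60%.

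Principal components were taken from log2 CPM with a prior count of 2 after removal of the batch effect with limma 3.58.1. The sign of the first component was set so that settled animals lie higher, and that of the second so that it rises with age. A settlement score was made per animal as the mean log2 CPM of the genes that rose on settlement minus that of the genes that fell. To keep the score apart from the animals it was applied to, larvae given one alga were scored with genes called in settled animals of the other alga. Scores and total counts were compared with exact permutation tests, and animals were exchanged within batches for the score, in place of the random resamples first intended, because the groups held fewer than 10 animals. Settled and swimming animals were never pooled in a group. Python 3.11.15 with SciPy 1.17.1, NumPy 2.4.6 and pandas 2.3.3 was used for these tests and matplotlib 3.10.9 for the plots.

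Genes are given by their identifiers because the files do not pair them with names, and a reference gene table of the species shared no identifiers with the count table. For the same reason no gene list, marker list or coordinate was tested or printed. The naming rule took, in each of 5 main comparisons, the 2 changed genes with the largest rise and the 2 with the largest fall in fitted log2 fold change among those with a mean of at least 20 CPM on the higher side. A gene named in one comparison is also given in others. The comparisons, the alternatives and this rule were fixed before the data were examined, and alternatives added later are named as such.

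Alternatives to the main analysis were the size factors of DESeq2 1.42.0 within edgeR, no filter on low counts, a filter on a mean count of at least 5, the test of DESeq2, no batch term, a block for the animal number, fits to the compared groups alone, and fits within each batch. For the score they were another prior count, 100 genes per direction and no removal of the batch effect. Each count of changed genes was also set against 40 splits of the compared animals, the real one included. The limit was 100, and 40 were drawn to keep the computing time short, a number chosen after the data were in hand. The smallest share they can give is 1 in 40. Alternatives added after seeing the data were a correction for shared identifiers, the log2 total count as a covariate, leaving out 5 animals with less than 50% of the median total, and leaving out the features that ever exceeded 4096 counts.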

Results

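Transcripts were counted in 144 single animals of the sponge Amphimedon queenslandica, a species whose brooded larvae swim before they settle and metamorphose. Larvae were given 1 of 3 cues in separate wells at 1.5, 3, 5 or 8 h after emergence from the mother. The cues were a piece of the articulated coralline alga Amphiroa fragilissima, a piece of the crustose coralline alga Mesophyllum sp., or filtered seawater as the control. Animals were collected 2 h later, so that the youngest were 3.5 h old and the others 5, 7 or 10 h. Larvae that were still swimming formed 12 groups of 9, one for each cue and age. Another 9 larvae were collected at 0.5 h without a cue. Settled post-larvae came from both algae at the induction ages of 5 and 8 h, with 6 animals on A. fragilissima induced at 5 h and 7 animals in each of the other 3 groups. Every animal was a separate individual. The design asks how transcript levels change with larval age, with exposure to each alga before settlement, and with settlement itself.

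Group means of the total count ran from 1460890 ± 326612 (SD, n = 9) in larvae with A. fragilissima at 3.5 h to 2431565 ± 894093 (SD, n = 9) in seawater larvae at 10 h. Larvae with A. fragilissima induced at 1.5 h had fewer counts than seawater larvae of that age, which had 2344984 ± 459223 (SD, n = 9; adjusted p = 0.00691, exact permutation test, 12 comparisons). At the induction age of 3 h the means were 1518185 ± 344556 and 2105717 ± 557311 (SD, n = 9 each; adjusted p = 0.0987, exact permutation test). The first principal component held 11.5% of the variance and ran from swimming to settled animals. Swimming larvae lay between -28.1 and 15.9 on it, with an SD of 7.13, and settled animals between -4.77 and 126, with an SD of 45.3. Of the 27 settled animals, 6 lay no higher than the highest swimming larva. Along this component settled animals thus varied far more among themselves than swimming larvae did. The second component (4.74%) had a mean of -13.3 ± 19.8 (SD, n = 9) in seawater larvae at 3.5 h and 27.1 ± 7.53 (SD, n = 9) at 10 h. Its SD was 13.7 to 26.7 within settled groups and 7.53 to 27.4 within swimming groups, so settled animals did not spread more widely on it.

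**Figure D1:**
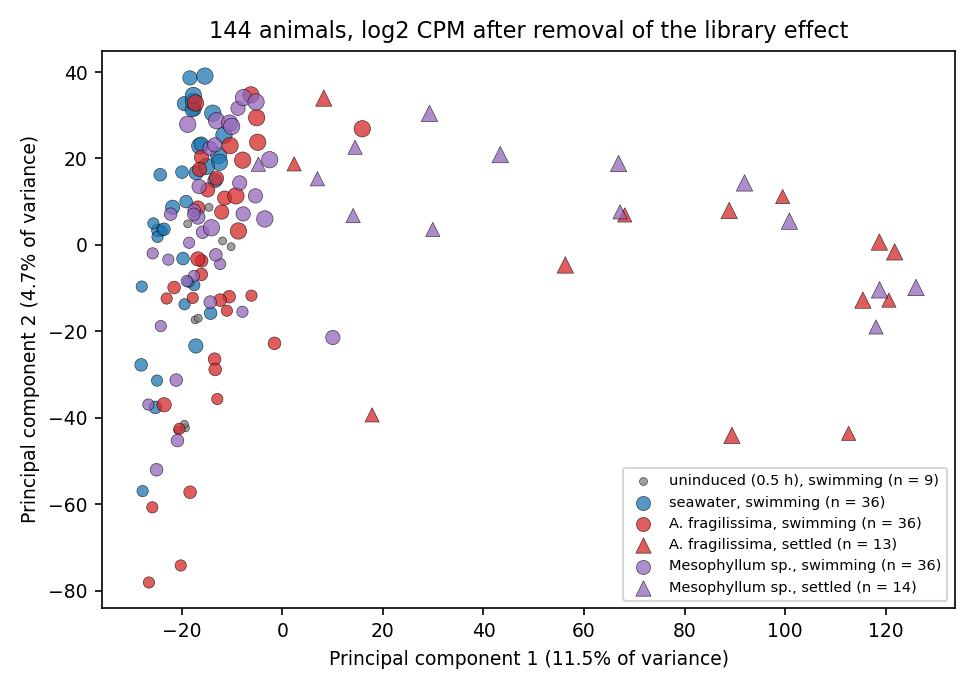
Each point is 1 of the 144 animals on the first 2 principal components (arbitrary units) of log2 CPM after removal of the batch effect, coloured by cue, with circles for swimming larvae, triangles for settled animals and larger points for older animals. Settled animals spread from -4.77 to 126 along the first component, and swimming larvae lie between -28.1 and 15.9.

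Larvae without an alga differed between ages in 2273 of 14950 genes tested over the 5 ages. The larvae of 0.5 h had not spent 2 h in wells, so age and handling cannot be told apart in comparisons with them. From 3.5 h on that handling was shared. Between 0.5 and 3.5 h 478 genes rose and 424 fell, and between 3.5 and 10 h 584 rose and 602 fell. The single steps within the later span had 4 changed genes between 3.5 and 5 h, 34 between 5 and 7 h and 18 between 7 and 10 h. Of the age genes, 33.7% had their highest fitted mean at 0.5 h (24.3% of all genes tested) and 27.3% at 10 h (25.4% of all). At 5 h the share was 9.37% (14.1% of all) and at 7 h 9.77% (16.2% of all). Between 0.5 and 10 h, 844 genes rose and 855 fell, among them 162 that rose and 148 that fell at least 4-fold.

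The named genes with the largest age changes were uneven among animals. Aqu2.1.20087_001 and Aqu2.1.22008_001 belong to the 104 genes, described below, that were present in some swimming larvae and absent in others. Aqu2.1.20087_001 was detected in 5 of 9 larvae at 10 h, with a mean of 23.1 ± 35.6 CPM (SD, n = 9) and a median of 0.184 CPM. It had no count in any of the 9 larvae at 0.5 h, so that its mean was at least 152-fold higher at 10 h (adjusted p = 0.00877, edgeR; 0.277 within batch T). Aqu2.1.22008_001 rose from 0.344 ± 0.569 to 34.5 ± 51.3 CPM (SD, n = 9 each), a log2 fold change of 6.88 ± 2.00 (SE; adjusted p = 0.0123, edgeR). Within batch T alone its log2 fold change was -1.67, with an adjusted p of 0.887 in edgeR. Aqu2.1.14449_001 fell from 34.97 ± 52.4 CPM, where 6 of 9 larvae had counts, to 0.527 ± 1.58 CPM, where 1 of 9 had counts (SD; adjusted p = 0.00131, edgeR; 0.151 within batch K). With Mesophyllum sp. it rose between 3.5 and 10 h, from 0.222 ± 0.665 to 25.7 ± 36.7 CPM (SD, n = 9 each), a log2 fold change of 8.78 ± 2.01 (SE; adjusted p = 0.00157, edgeR). Aqu2.1.13974_001 fell from 76.9 ± 113 to 1.84 ± 4.18 CPM (SD, n = 9 each; adjusted p = 0.0211, edgeR), and its call was lost within T (adjusted p = 0.0846) and within K (adjusted p = 0.216). Within batch T, which held 4 animals at each of the 2 ages, 387 genes changed between 0.5 and 10 h, 359 of them shared with the full fit. Within K, which held 5 and 5, 1134 genes changed between these ages, 916 of them shared. Between 3.5 and 10 h, T gave 282 changed genes and K gave 369.

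Larvae still swimming with A. fragilissima differed from seawater larvae in 822 genes, taken over the 4 ages. A response to the alga and selection of the larvae that had not settled were not told apart. In the main scaling 347 of the 822 genes rose and 475 fell. With DESeq2 size factors 427 rose and 347 fell of 774, so the balance of directions depends on the scaling. Changes were mostly small, with a median log2 fold change of 0.57 among the genes that rose and -0.33 among those that fell. At least 4-fold changes were found in 26 genes that rose and 10 that fell. Of the 347 that rose, 286 had a positive fold change at each of the 4 ages, and of the 475 that fell, 373 had a negative one at each.

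Aqu2.1.42041_001 stood out by its evenness and was detected in all 36 exposed larvae. Its level was 34.8 ± 30.2 CPM with A. fragilissima and 5.23 ± 4.52 CPM in seawater (SD, n = 36 each), a log2 fold change of 2.61 ± 0.27 (SE; adjusted p = 8.84e-13). Larvae induced at 1.5 h already had 18.8 ± 9.17 CPM against 2.50 ± 1.66 (SD, n = 9 each; adjusted p = 0.0019, edgeR). After induction at 5 h the levels were 61.6 ± 35.3 against 7.40 ± 3.81 CPM (SD, n = 9 each; adjusted p = 0.000496, edgeR), and after 8 h 40.1 ± 33.3 against 4.57 ± 2.31 CPM (SD, n = 9 each; adjusted p = 0.00161, edgeR). At 3 h the difference did not pass the test, with 18.5 ± 11.1 against 6.47 ± 7.14 CPM (SD, n = 9 each; adjusted p = 0.144, edgeR). Within batches T and K its log2 fold change was 2.46 and 2.86, with adjusted p of 4.33e-05 and 5.47e-07 in edgeR. Aqu2.1.35939_001 fell from 53.8 ± 66.6 to 12.7 ± 18.2 CPM (SD, n = 36 each), a log2 fold change of -2.18 ± 0.38 (SE; adjusted p = 1.35e-05). In seawater this gene fell from 40.3 ± 22.4 CPM at 0.5 h to 7.34 ± 8.78 CPM at 3.5 h (SD, n = 9 each; adjusted p = 0.0205, edgeR) and rose from there to 78.2 ± 62.7 CPM at 10 h (SD, n = 9; adjusted p = 0.000402, edgeR). The other named genes were uneven. Aqu2.1.29756_001 was detected in 26 of 36 exposed and 17 of 36 seawater larvae, with medians of 0.619 and 0 CPM (adjusted p = 0.00655). Aqu2.1.26561_001 had means of 6.26 ± 33.6 and 43.8 ± 135 CPM (SD, n = 36 each) and was detected in 18 of 36 larvae on both sides (adjusted p = 0.00916), with medians of 0.199 and 0.0920 CPM that run against the fall of the means. The call of the former was lost within T and K and with depth as a covariate (adjusted p = 0.608, 0.286 and 0.48), and that of the latter within K (adjusted p = 0.325).

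By age, the difference between A. fragilissima and seawater comprised 158 genes after induction at 1.5 h, 180 at 3 h, 47 at 5 h and 17 at 8 h. The order of ages was not kept, with 74, 138, 151 and 17 in fits to the compared groups alone and 74, 37, 155 and 69 within batch K. A test of whether the cue effect depended on age called 52 genes, but chance cannot be excluded. A fit to the compared groups gave 37 genes, and 5 of 40 splits of these animals, the real one included, gave as many. Within batch T, with 3 or 4 exposed larvae per age, 165 genes changed over the 4 ages, and within K 983 changed. Batch C held 1 seawater larva, so it gave no such comparison. A fit to the 2 compared cues alone gave 1264 genes, of which 750 were in the main list.

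**Figure D2:**
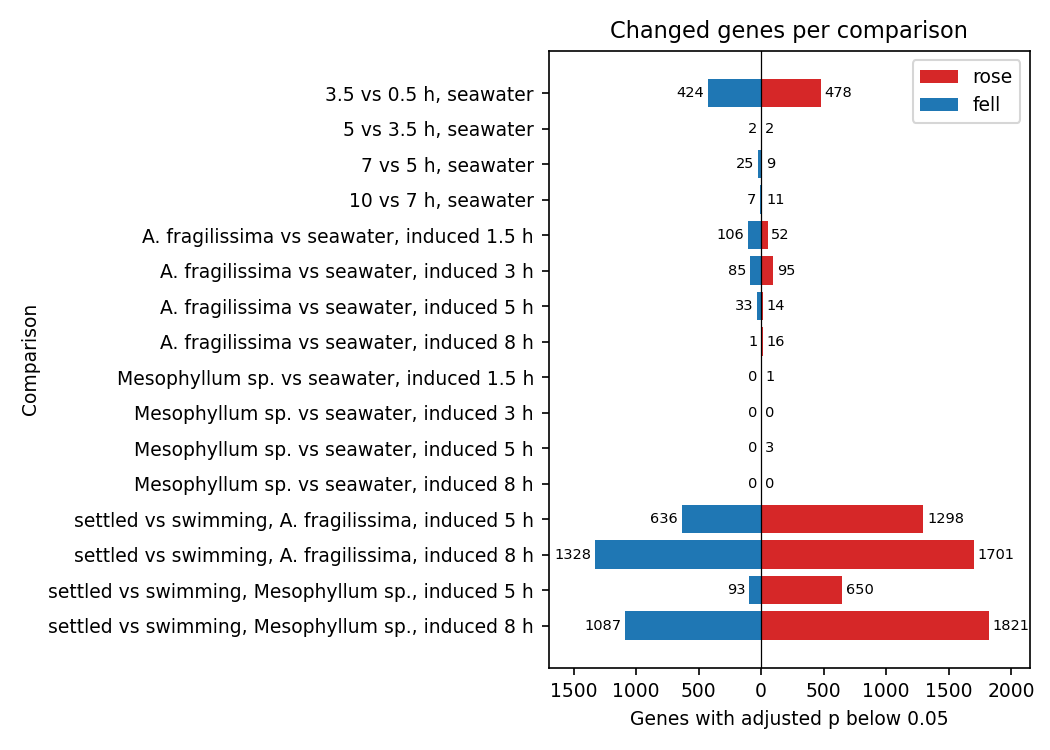
Bars give the number of genes with an adjusted p below 0.05 that rose (red, right) or fell (blue, left) in each comparison of edgeR, with induction ages in h. Swimming larvae with A. fragilissima differed from seawater larvae in 17 to 180 genes at single ages and those with Mesophyllum sp. in 0 to 3. Settled and swimming animals differed in 743 to 3029.

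Swimming larvae with Mesophyllum sp. differed from seawater larvae in 32 genes over the 4 ages, with 26 that rose and 6 that fell. Aqu2.1.35939_001 fell here as well, from 53.8 ± 66.6 to 16.2 ± 22.3 CPM (SD, n = 36 each), a log2 fold change of -1.64 ± 0.40 (SE; adjusted p = 0.0416). Aqu2.1.30896_001 fell from 119 ± 18.5 to 91.4 ± 17.8 CPM (SD, n = 36 each; adjusted p = 0.0173), and it had a log2 fold change of -0.27 ± 0.07 (SE) with A. fragilissima (adjusted p = 0.00423). Aqu2.1.25609_001 rose from 23.1 ± 35.6 to 50.9 ± 64.0 CPM (SD, n = 36 each; adjusted p = 0.0344). Aqu2.1.30516_001 had a mean of 29.5 ± 81.0 CPM with the alga and 5.86 ± 10.2 CPM in seawater (SD, n = 36 each; adjusted p = 0.0157), yet it was detected in 17 and 18 of 36 larvae, with medians of 0 and 0.194 CPM. This gene also belongs to the 104 present in some swimming larvae and absent in others. The calls of all 4 genes were lost within batch T, where adjusted p ran up to 0.589.

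At single ages edgeR called 1, 0, 3 and 0 genes for Mesophyllum sp. at 1.5, 3, 5 and 8 h, with 847, 853, 822 and 909 genes at an unadjusted p below 0.05. DESeq2 called 17, 12, 11 and 16. Without the batch term 123 genes were called over the 4 ages, and within batch T 3 were called.

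The algae differed directly in 122 genes, 63 higher and 59 lower with A. fragilissima. Aqu2.1.42041_001 separated them, at 34.8 ± 30.2 CPM with A. fragilissima and 7.03 ± 14.002 CPM with Mesophyllum sp. (SD, n = 36 each), a log2 fold change of 2.61 ± 0.29 (SE; adjusted p = 6.09e-11). Aqu2.1.16067_001 was lower with A. fragilissima, at 8.80 ± 19.8 against 33.3 ± 38.2 CPM (SD, n = 36 each; adjusted p = 0.0309). Aqu2.1.25658_001 was higher, with medians of 1.87 and 1.22 CPM, at the limit of the test (adjusted p = 0.04997, and up to 0.707 within batch T). Aqu2.1.06371_001 was lower, with medians of 0.641 and 0.882 CPM (adjusted p = 0.0227, and 0.727 with depth as a covariate). By age 61, 30, 0 and 6 genes differed between the algae at 1.5, 3, 5 and 8 h. At 5 h 655 genes had an unadjusted p below 0.05 and DESeq2 called 2. Within batch T 62 genes differed over the 4 ages, and without the batch term 381 did.

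The genes called with A. fragilissima mostly had the same sign with Mesophyllum sp. To avoid shared controls, the seawater larvae were split into separate sets for the 2 algae, 5 times over. The share of genes called with A. fragilissima that had the same sign with Mesophyllum sp. was then 85.2% to 90.4%. The slope of the fold changes with Mesophyllum sp. on those with A. fragilissima was 0.13 to 0.31. Over all genes the correlation of the fold changes was 0.18 to 0.27. Both algae still shared the batch term of each fit, and 1 of 36 seawater larvae was in batch C. An error in that term could move both comparisons the same way.

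Settlement changed 5087 of 14950 genes over both algae and ages, of which 2524 rose and 2563 fell. That fit used 1 spread per gene for all animals. Since settled animals varied more along the first principal component (SD 45.3 against 7.13), adjusted p for settlement may be too small. A fit to the compared animals alone gave 4210 genes, and other splits of them gave up to 656. Large changes were mainly rises, with 438 genes that rose and 77 that fell at least 4-fold, and 209 against 14 at least 8-fold. A set of 14 genes went from a mean below 1 CPM in swimming larvae to at least 20 CPM in settled animals. Of the genes that rose, 2289 had a positive fold change in each of the 4 comparisons of settled with swimming animals, and of those that fell 2236 had a negative one in each. In all 4 comparisons of the fit to all animals 495 genes rose and 17 fell with an adjusted p below 0.05. These comparisons are not separate replications. Settlement on Mesophyllum sp. after induction at 5 h called 0 genes when fitted alone. On A. fragilissima after induction at 5 h no batch held both stages.

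Aqu2.1.00134_001 was at 84.8 ± 81.7 CPM in settled animals (SD, n = 27) and 0.216 ± 0.611 CPM in swimming larvae of the same algae and ages (SD, n = 36), a ratio of means of 392 (adjusted p = 8.24e-18). It was detected in 26 of 27 settled and 6 of 36 swimming animals. Its mean was 20.7 ± 37.3 CPM in animals settled on Mesophyllum sp. after induction at 5 h and 106 ± 100 CPM after induction at 8 h (SD, n = 7 each), and 96.3 ± 79.7 (SD, n = 6) and 118 ± 74.1 CPM (SD, n = 7) on A. fragilissima. Its change on settlement was not shown to differ between the ages (adjusted p = 0.911, edgeR). Aqu2.1.31172_001 was detected in 15 of 27 settled and 5 of 36 swimming animals, at 64.9 ± 120 and 0.0879 ± 0.241 CPM (SD), a ratio of means of 739 (adjusted p = 1.26e-09). Aqu2.1.04208_001 fell from 35.2 ± 47.3 CPM (SD, n = 36) to 5.72 ± 18.4 CPM (SD, n = 27; adjusted p = 8.29e-05). Aqu2.1.22008_001, which rose with age in seawater, was detected in 15 of 36 swimming and 8 of 27 settled animals, at 25.3 ± 51.2 and 5.17 ± 24.3 CPM (SD; adjusted p = 0.0228). A fit to the compared groups alone gave this last gene an adjusted p of 0.0846.

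Aqu2.1.42041_001, the transcript raised in larvae near A. fragilissima, was highest in settled animals. Its mean was 176 ± 119 CPM (SD, n = 6) and 97.5 ± 51.1 CPM (SD, n = 7) on A. fragilissima after induction at 5 and 8 h, and 177 ± 170 and 116 ± 61.7 CPM (SD, n = 7 each) on Mesophyllum sp. Swimming larvae with Mesophyllum sp. had 16.5 ± 26.0 and 7.01 ± 5.05 CPM at those ages (SD, n = 9 each). The rise from swimming to settled on Mesophyllum sp. had a log2 fold change of 3.71 ± 0.39 (SE; adjusted p = 2.41e-14) and that on A. fragilissima of 1.31 ± 0.46 (SE; adjusted p = 0.0258). The 2 rises lay further apart than their standard errors, but their difference did not pass after adjustment over the 14950 genes tested (adjusted p = 0.116, edgeR).

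**Figure D3:**
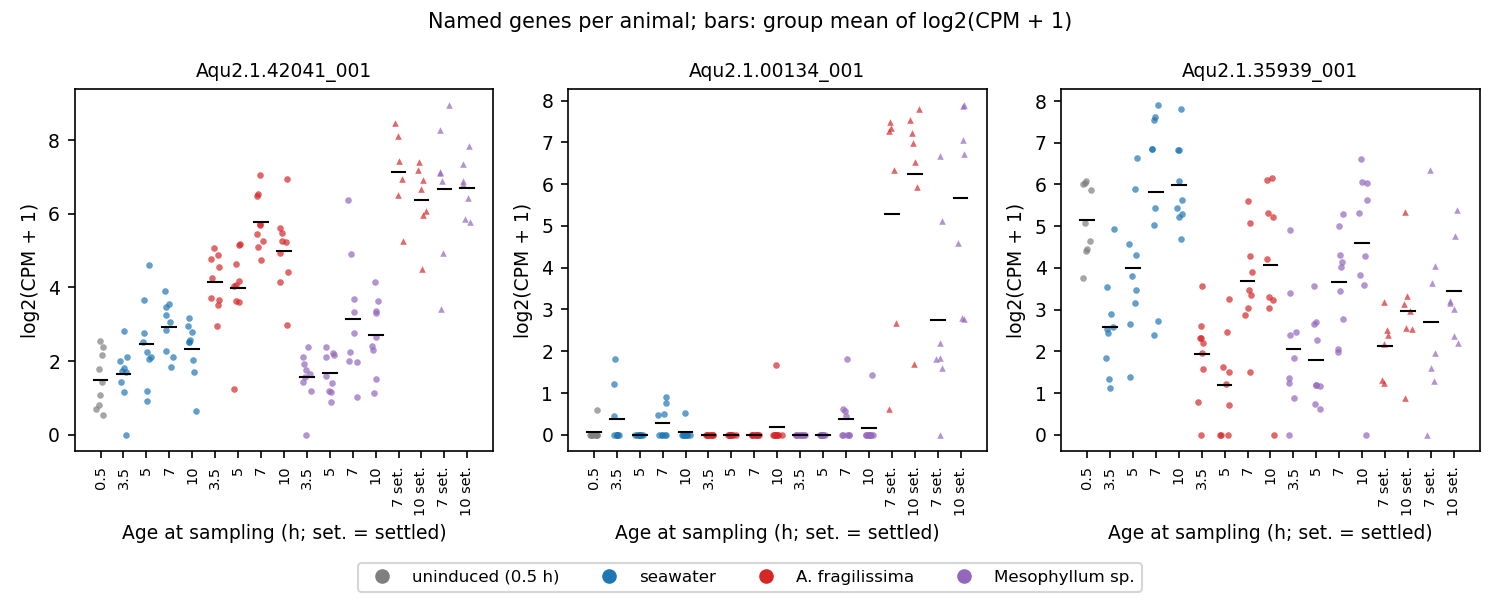
Log2 (CPM + 1) of 3 named genes in each animal, by age at collection in h, with colours for the cue, circles for swimming and triangles for settled (set.) animals, and a bar at each group mean. Aqu2.1.42041_001 averages 34.8 CPM in swimming larvae with A. fragilissima and 5.23 CPM in seawater, Aqu2.1.00134_001 is nearly limited to settled animals, and Aqu2.1.35939_001 is lower with both algae.

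Counts for single comparisons of settled with swimming animals were 1934 on A. fragilissima and 743 on Mesophyllum sp. after induction at 5 h, and 3029 and 2908 after induction at 8 h. They depended on which animals entered the fit and on the batch term. Fits to the 2 compared groups alone gave 734, 0, 644 and 1279 in that order. Without a batch term such a fit gave 1757 for A. fragilissima at 5 h. Neither of these fits to that comparison alone can tell settlement from batch C. Over both algae and ages a fit to the compared groups with the batch term gave 4210 genes, 3971 of them shared with the main list. Within batch C, which held 25 of the 27 settled animals, settlement after induction at 8 h changed 500 genes on A. fragilissima and 1490 on Mesophyllum sp., and settlement on Mesophyllum sp. after induction at 5 h changed 0 in edgeR (5 against 6 animals). For that last comparison the fit to all animals had 2388 genes at an unadjusted p below 0.05 and DESeq2 on all animals called 843. On A. fragilissima at 5 h all 6 settled animals were in C and no swimming larva was, so that no batch held both.

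Genes changed by settlement went the same way on both algae in 2297 of the 2298 genes called on both, which involved different animals. By chance 257 genes would have risen on both and 1527 did, and 144 would have fallen on both and 770 did. Settlement differed between the algae in 3 genes and between the induction ages in 91 genes, 55 with a more positive fold change at 8 h. Animals settled on A. fragilissima and on Mesophyllum sp. differed in 64 genes. None of the last 3 counts was kept in fits to the compared groups alone, which gave 0, 5 and 0.

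Genes that changed between 0.5 and 10 h, a span in which age and handling were not told apart, and with settlement mostly moved in opposite directions. Of 780 genes called in both, 291 went the same way. The largest class, of 289 genes, fell between 0.5 and 10 h and rose on settlement, where 144 would be expected by chance. A further 200 rose with age and fell on settlement, where 145 would be expected. Genes that rose in swimming larvae with A. fragilissima were over-represented among those that rose on settlement on Mesophyllum sp., with 156 genes where 44.8 would be expected, and 11 fell where 28.3 would be expected. Those that fell with A. fragilissima were found among both the fallen (56, expected 38.7) and the risen (120, expected 61.3). The share in the same direction was 61.8% of 343, but it was 67.8% with DESeq2 size factors and 52.6% with depth as a covariate. These overlaps involve no shared animals, but the comparisons share the batch term of the fit.

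The settlement score compares larvae still swimming near an alga with seawater larvae of the same age in the genes that change on settlement. A higher score alone does not show movement toward the settled state, because unexposed larvae of 0.5 h scored 0.52 ± 0.07 with genes from Mesophyllum sp. and 0.33 ± 0.06 with genes from A. fragilissima (SD, n = 9). These values exceed the 0.45 of larvae with A. fragilissima at 5 h and the 0.22, 0.22, 0.28 and 0.22 of larvae with Mesophyllum sp. With A. fragilissima the score exceeded that of seawater larvae by 0.21 after induction at 8 h (0.61 ± 0.17 against 0.40 ± 0.06, SD, n = 9 each; adjusted p = 0.0327, exact permutation test within batches, 8 comparisons) and by 0.08 after 5 h (0.45 ± 0.06 against 0.37 ± 0.04, SD, n = 9 each; adjusted p = 0.0354, exact). After 3 h the difference was 0.18 (adjusted p = 0.0541, exact) and after 1.5 h 0.09 (adjusted p = 0.261, exact). With Mesophyllum sp. it was 0.10 after 3 h (0.22 ± 0.05 against 0.12 ± 0.06, SD, n = 9 each; adjusted p = 0.0435, exact) and 0.05 after 1.5 h (adjusted p = 0.281, exact). The differences of 0.19 after 5 h and 0.10 after 8 h (adjusted p of 0.251 and 0.314, exact) rest partly on 5 and 10 larvae in batches without the other group, which the test could not exchange. It had 140 and 70 arrangements there, and after 8 h it speaks for batch T alone. In the other comparisons 1 to 3 larvae could not be exchanged. Within shared batches the differences were 0.07, 0.13, 0.08 and 0.20 with A. fragilissima after 1.5, 3, 5 and 8 h, and 0.05, 0.08, 0.08 and 0.10 with Mesophyllum sp. Settled animals scored 2.33 ± 1.08 (SD, n = 6) and 2.63 ± 0.93 (SD, n = 7) on A. fragilissima, and 1.19 ± 1.02 and 2.23 ± 0.95 (SD, n = 7 each) on Mesophyllum sp., after induction at 5 and 8 h. The difference between the ages on Mesophyllum sp. did not pass a test (adjusted p = 0.152, exact permutation test, 2 comparisons). Unlike for the larvae, all animals were exchanged there without regard to batch. Batch T held 3 to 5 larvae per side, too few for a single comparison to pass after adjustment over 8. There the differences with A. fragilissima were -0.0530, 0.0801, 0.105 and 0.0738 after 1.5, 3, 5 and 8 h, that after 5 h with the smallest p that 35 arrangements allow (p = 0.0286, exact; adjusted p = 0.229). Without removal of the batch effect the differences with Mesophyllum sp. were 0.0231, 0.0473, 0.113 and 0.0228 after 1.5, 3, 5 and 8 h, and p stays the same because animals were exchanged within batches. With 100 genes per direction all 4 differences for A. fragilissima passed, at 0.35, 0.50, 0.21 and 0.53.

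**Figure D4:**
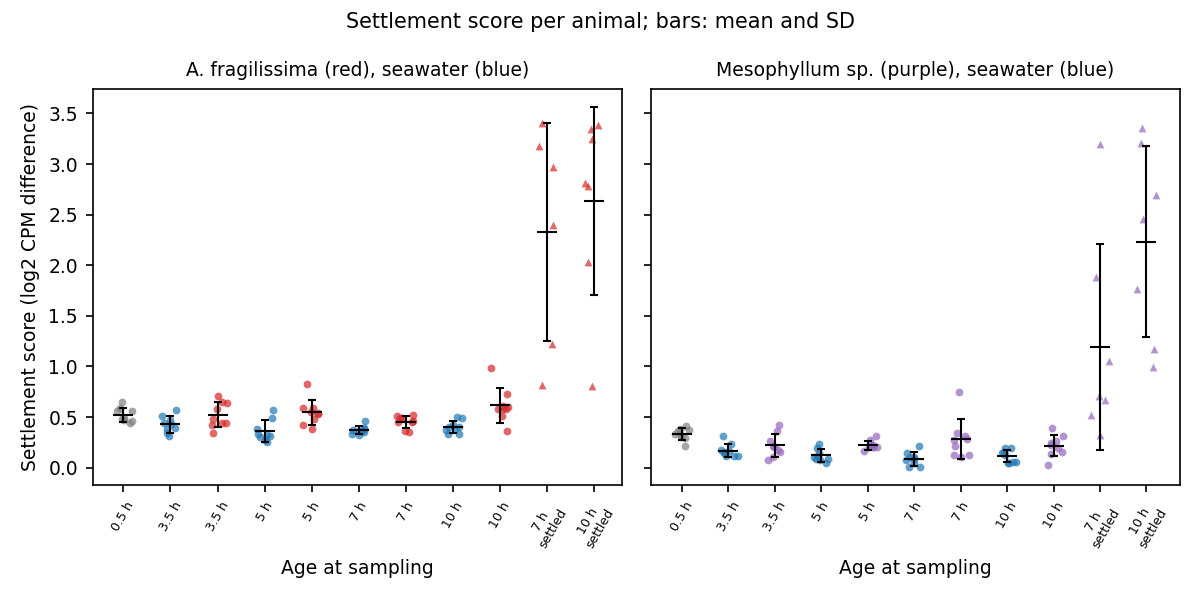
Settlement score (difference of mean log2 CPM) of each animal by age at collection in h, for A. fragilissima scored with genes from Mesophyllum sp. (left) and the reverse (right), with bars for the group mean and SD. Settled animals average 1.19 to 2.63 and swimming larvae with either alga 0.22 to 0.61.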

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

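The tests of batch within C for Mesophyllum sp. at 8 h, of depth as a covariate, of batch T for the algae, of the score of settled animals within batches, and of batch and shared parentage for genes present in part of the larvae were chosen after the results were seen.

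Settled animals differed from swimming larvae in 5087 genes, while 25 of the 27 settled animals were in batch C. Batch as the whole cause is argued against on Mesophyllum sp. at 8 h by 1490 genes changed within C alone, and on A. fragilissima at 5 h by 97.5% of the genes changed there (1880 of 1929) having the same sign on Mesophyllum sp. at 8 h within C. Depth as the whole cause is argued against by 5142 genes with log2 total count as a covariate. On Mesophyllum sp. at 5 h, 73.4% of the genes changed on A. fragilissima (2753 of 3752) kept their sign within C. That share lay between the bounds set beforehand and decides nothing alone, and edgeR called 0 genes there. Within C and T the score with genes from A. fragilissima was 0.90 higher in the 7 settled than in the 9 swimming animals. The adjusted p was 0.00568 (exact permutation test, 3 comparisons). Since animals were exchanged within batches, this argues against batch as the whole cause of the shift in these genes. The ranges overlapped in C, at 0.32 to 1.89 in 5 settled and 0.22 to 0.75 in 6 swimming animals. In T the 2 settled animals scored 0.52 and 3.19 and the 3 swimming larvae 0.10 to 0.13. A biological difference between stages may account for the rest, as a hypothesis.

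Swimming larvae differed from seawater larvae in 822 genes with A. fragilissima and in 32 with Mesophyllum sp., and the direct test called 122 genes that differed between the algae. The lower depth of larvae with A. fragilissima predicted -1.75% of the shift in its genes, with an upper bound of 3.50%, which argues against depth. Within batch T alone 165 genes changed with A. fragilissima and 3 with Mesophyllum sp., which argues against the spread of cues over batches. Genes present in part of the larvae made up 0.243% of the 822 (2 genes), but the 104 such genes could give 12.7% at most, so that share decides nothing. A response to the alga itself and selection of the larvae that had not settled stay open, as untested.

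In swimming larvae 104 genes were either at 20 CPM or more or below 1 CPM in many of the 117 animals, with a median of 45.3% of animals above 5 CPM. Total counts differed by 0.0206 (median log2, animals without the transcript minus those with it), which argues against low depth. Profiles of these genes were more alike within a batch than between batches by 0.00353, which argues against batch. After shuffling linked genes together in 91 blocks, 133 pairs of larvae exceeded a similarity that 6.79 would exceed by chance, 19.6 times as many, and 14 of these pairs shared a group. Shared parentage of some larvae may explain this, as a hypothesis that the labels do not allow to be checked, and linkage of genes beyond the blocks stays open.

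Of 93 tests for a single animal far from its group, 12 found one, and chance flags about 1 in 20 groups. These tests also used scores with genes from an animal's own alga, which are not kept apart from that animal. Flags of 1 animal by score and by first component are not separate findings. With A. fragilissima at 3 h, replicate 5 had 15436 features detected (next 17427) and replicate 13 a score of 0.83 with genes from Mesophyllum sp. (next 0.59). With A. fragilissima at 5 h, swimming replicate 9 was at -23.5 on the first component (next -16.8). With Mesophyllum sp. at 5 h, swimming replicate 11 had 20506 features (next 19160), and swimming replicate 10 had scores of 0.85 (next 0.52) and 0.75 (next 0.34) with the genes from Mesophyllum sp. and A. fragilissima, and 10.0 (next -5.35) on the first component. With A. fragilissima at 8 h, swimming replicate 10 had a score of 0.64 (next 0.27) with genes from A. fragilissima and 15.9 (next -4.91) on the first component. In seawater at 8 h, replicate 2 had a total of 4692279 (next 2575138), Aqu2.1.14449_001 had a log2 CPM of 2.52 in replicate 10 (next 0.00), and Aqu2.1.13974_001 one of 3.80 in replicate 8 (next 1.21).

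In the fit to all animals edgeR called 52 genes for a cue effect that depends on age, 3 for a difference of settlement between algae, 91 for one between induction ages, and 122 for a difference between the algae. Fits to the compared groups alone gave 37, 0, 5 and 193. Only for the algae did no other split below give as many genes, so the first 3 differences stay open.

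Each count of changed genes was set against 40 splits of the compared animals, the real one included, with fits to those animals alone. Animals were exchanged without regard to batch, so the splits do not test batch. A share of 1 in 40 is the smallest possible and was not adjusted over the comparisons. It argues against chance for a count, weakly so for small counts, without excluding it. That share was reached where only the real split gave as many genes. This held for age over all ages (2831, highest other 6), 10 against 0.5 h (1764, 0), 10 against 3.5 h (1316, 1), 3.5 against 0.5 h (1104, 0), 5 against 3.5 h (3, 1) and 10 against 7 h (9, 1). It held for A. fragilissima at 1.5, 3, 5 and 8 h (74, 138, 151 and 17, highest others 4, 0, 4 and 0) and over ages (1264, 3), for Mesophyllum sp. over ages (29, 9), and for the algae against each other over ages (193, 10), at 1.5 h (25, 2) and at 3 h (37, 2). It held for settlement over all groups (4210, 656), and on A. fragilissima at 5 h without a batch term (1757, 1) and at 8 h (644, 121). The splits alone do not exclude chance for settlement on Mesophyllum sp. at 8 h (1279, highest other 1361, 2 splits as large), where the highest split kept 5 of the 7 settled animals together. Other animals argue against chance there: with genes taken from animals of A. fragilissima the score was 0.99 to 3.36 in the 7 settled animals and 0.03 to 0.39 in the 9 swimming larvae, with a difference of 2.02 within C (7 against 5; adjusted p = 0.00568, exact). Chance cannot be excluded for 7 against 5 h (31, 33, 2 splits), for the dependence of the cue effect on age (37, 52, 5 splits) or for the difference of settlement between ages (5, 346, 5 splits). What gave 346 genes in 1 split was not tested. Where edgeR called 0 in these fits, all 40 splits give as many by construction, and the splits say nothing about chance: Mesophyllum sp. at 1.5, 3, 5 and 8 h (highest other 1 each), the algae against each other at 5 and 8 h (2 and 1), settlement on Mesophyllum sp. at 5 h (8), its difference between algae (6) and settled animals of the 2 algae (1). In the fit to all animals these had 847, 853, 822, 909, 655, 834, 2388, 1098 and 1910 genes at an unadjusted p below 0.05, and DESeq2 called 17, 12, 11, 16, 2, 13, 843, 15 and 165.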

How the results depend on the processing

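The correction for shared identifiers, depth as a covariate and the removal of low-depth animals or of features near the count ceiling were chosen after seeing the data. The count for settlement over all groups stayed within 1.5 times 5087 in each alternative run except the block, and the count for A. fragilissima over ages (822) in each except batch T (165) and fits to the compared groups (1264). The settlement score kept its calls with a prior count of 0.5. Without removal of the batch effect its p cannot change, since animals were exchanged within batches, but the differences for Mesophyllum sp. at 1.5, 3, 5 and 8 h went from 0.05, 0.10, 0.19 and 0.10 to 0.0231, 0.0473, 0.113 and 0.0228. Counts at single ages, the 32 genes of Mesophyllum sp., the dependence of the cue effect on age and the differences among settled animals moved more than 1.5 times in several alternatives. No animal had a total under the depth limit of 502842 counts, so that alternative was not run, and gene lists could not be run without names. Fits within a batch use fewer animals; for the other alternatives the cause was not tested. In simulations 26% of 2-fold changes were recovered at a single induction age and 26% between 0.5 and 10 h; depth and number of animals were not separated.

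Within batch T the age counts were 449 over all ages, 387 for 10 against 0.5 h and 282 for 10 against 3.5 h. At 1.5, 3, 5 and 8 h A. fragilissima gave 10, 14, 0 and 0 there and Mesophyllum sp. 6, 1, 0 and 1, with 165 and 3 over ages, 62 between the algae and 0 for the dependence of the cue effect on age. Aqu2.1.22008_001 reversed with age in T, to -1.67. The score difference in T was -0.0530, 0.0801, 0.105 and 0.0738 for A. fragilissima at 1.5, 3, 5 and 8 h, and 0.0791 for Mesophyllum sp. at 3 h, where no single comparison could pass after adjustment. Within batch K the counts were 1454 over all ages, 369 for 10 against 3.5 h, 74, 37, 155 and 69 for A. fragilissima at 1.5, 3, 5 and 8 h, and 15 for Mesophyllum sp. at 1.5 h. Within batch C settlement gave 0 on Mesophyllum sp. at 5 h, 500 on A. fragilissima at 8 h, 1490 on Mesophyllum sp. at 8 h, and 0 between settled animals of the algae.

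Fits to the compared groups alone gave 74 for A. fragilissima at 1.5 h, 151 at 5 h and 1264 over ages, 0 for Mesophyllum sp. at 1.5 h and 0 at 5 h, and 193 between the algae. For settlement they gave 734 and 644 on A. fragilissima at 5 and 8 h, 0 and 1279 on Mesophyllum sp., 0 for the difference between algae, 5 between ages and 0 between settled animals. On A. fragilissima at 5 h such a fit cannot tell settlement from batch C, and without a batch term it gave 1757. Without the batch term Mesophyllum sp. gave 3, 13 and 5 at 3, 5 and 8 h and 123 over ages, the algae differed in 381, the cue effect depended on age in 110, settlement differed between algae in 12, and settled animals differed in 40.

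DESeq2 gave 17, 12, 11 and 16 for Mesophyllum sp. at 1.5, 3, 5 and 8 h and 57 over ages, 282, 105 and 49 for A. fragilissima at 3, 5 and 8 h, 186 between the algae, 15 and 166 for the differences of settlement between algae and ages, and 165 between settled animals. Its size factors in edgeR gave 1 for Mesophyllum sp. at 8 h. Without a filter Mesophyllum sp. gave 4 at 1.5 h, 7 at 8 h and 19 over ages, A. fragilissima 25 at 5 h and 6 at 8 h, the algae 81, the dependence on age 143, the differences of settlement 1 and 52, and settled animals 41. With a mean count of at least 5, Mesophyllum sp. gave 1 at 8 h and the difference of settlement between algae 0. With depth as a covariate, Mesophyllum sp. gave 0 at 1.5 h, A. fragilissima 76 at 5 h and settled animals 26. Without low-depth animals, Mesophyllum sp. gave 0 at 1.5 h and 20 over ages, and settled animals 20. With shared identifiers corrected, A. fragilissima gave 82 at 5 h, and Mesophyllum sp. 5 at 5 h, 1 at 8 h and 61 over ages. Without features near the count ceiling, A. fragilissima gave 18 at 5 h and Mesophyllum sp. 0 at 5 h. With 100 genes per direction the score of A. fragilissima passed at 1.5 h (0.35) and 3 h (0.50).

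Animal numbers did not pair the samples, since 868 same-number pairs had a median correlation of -0.0117 and 17 of 144 animals were closest to one of their own number. A block for the number gave 0 for Mesophyllum sp. at 5 h and 10 over ages, 9 for A. fragilissima at 8 h, 10 for the dependence on age, 1451 for settlement on A. fragilissima at 8 h, 2891 over all groups, 0 and 13 for its differences between algae and ages, and 15 between settled animals. The share of genes in the same direction with A. fragilissima and on settlement on Mesophyllum sp. reversed to 47.04% with the block.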

Other observations

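The comparison of neighbouring identifiers and that of the differences with A. fragilissima and with age were chosen after the data had been seen.

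Genes changed on settlement lay close together in the numbering of the gene models. Of 8428 pairs of tested genes with consecutive numbers, 1057 changed in the same direction on settlement. After 1000 shuffles of the calls the mean was 492 and the highest 561, so the observed number was 2.15 times the mean. Features whose identifiers have the other form made up 424 of the tested features, and 123 of them changed on settlement.

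Among genes called in both comparisons, the differences between A. fragilissima and seawater mostly ran against the course of age in other animals. Of 133 genes called both with A. fragilissima in swimming larvae and between 3.5 and 10 h with Mesophyllum sp., 13.5% went the same way. The opposition was weaker beyond these genes. Of all genes called with A. fragilissima, 31.6% had the same sign with age. Over all genes tested the correlation of the fold changes was -0.09 (Pearson) and -0.20 (Spearman). Genes that rose with A. fragilissima and fell with age numbered 55, where 11.4 would be expected, and 60 fell with the alga and rose with age, where 13.8 would be expected. No animals were shared between these comparisons, but both used the batch term of the same fit.

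The batches differed from each other in many genes once group was taken into account, with 2035 between K and T and 1837 between C and T.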
